A study of Mus musculus with 6 samples.

How the data were processed

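The series measured RNA from mouse bone marrow stromal cells of wild-type (WT) mice and of mice in which the long non-coding RNA gene NONMMUT002667 was knocked out (KO). There were 3 WT and 3 KO samples, each hybridised with 1 colour (Cy3) to 1 Agilent array, and the groups and replicate numbers were taken from the sample titles. Per the labels' protocols, femurs were crushed and digested with collagenase, cells positive for Sca-1 and CD29 and negative for CD45 and CD11b were sorted, and the sorted cells were grown to the first passage. The labels are not uniform: the description field and the extraction protocol speak of human blood, while the titles, source names, organism field and series text all speak of mouse stromal cells. The titles, source names and series text were followed. The labels number the mice or samples of a group without saying how many animals each sample held, so p-values measure the spread between these 6 samples.

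The intensity values of each spot are the scanner software's background-corrected processed signal, mean signal and median background, per the file headers. The file headers name Agilent Feature Extraction 10.7.1.1, and the submitters' processing notes name Agilent Feature Extraction 9.1. The arrays hold 62976 spots each, of which 59305 are not controls, for 56605 different probes, and the probe positions in the files refer to the mouse genome build mm9. The deposited series table holds log2 values. Its log2 columns correlated with the log2 processed signals of their own arrays with r between 0.9999 and 1.0 over the probes well above background, and every column held the same sorted values with a median of 6.15 over all rows, which is what quantile normalization gives. Whether further steps were applied to that table is not given in the sources used here.

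Probes were named through their accession in a RefSeq table for assembly GRCm38.p6, used for names only. Of the 56605 probes, 32994 were named by accession, 10224 by a symbol in that table and 520 by a synonym, while 2408 kept the name in the file and 10459 had no gene name. For the main fit, log2 of the processed signal minus the array's 75th percentile of that value over non-control probes was used. Spots marked as non-uniform or population outliers (49 to 131 per array) were left out and the remaining spots of a probe were averaged. A probe was tested if each group had at least 2 values and if it was well above background on every array of at least 1 group. For probes with several spots, at least a share of 0.5 of the spots had to be well above background. This left 28607 probes for 15324 gene symbols. Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided, group as the only term, 4 residual and 2.65 prior degrees of freedom) and Benjamini-Hochberg adjustment over all probes, with 0.05 as the threshold. A gene was represented by its tested probe with the highest mean over all 6 arrays, a choice blind to the groups. A bright probe can be one that also binds other transcripts, so disagreement between probes is given where it was seen. Where a probe was not well above background on any array of a group, only a lower bound of the fold is given. It is the mean of the bright group minus the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. The limma p of such a probe was computed on its signals as measured, not on the bound, so it rests in part on signals not well above background. Values below are log2 signals relative to the array's 75th percentile, as mean and SD over 3 arrays, unless stated otherwise.

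A set of 27 gene lists for programs and cell types was fixed before the data were examined, as were the groups, the test, the processing alternatives and the rule for naming genes. Lists were tested with camera in limma at a preset correlation of 0.01, with an estimated correlation, and with fry, each adjusted over the 27 lists. The interval of a list's median is a 95% bootstrap interval over its members from 10000 draws. Named genes are, per direction, up to 12 with the largest difference among those past the threshold whose groups do not overlap. Where fewer than 5 qualified, the genes with the smallest unadjusted p filled up to 5. Up to 4 members per list with the smallest p, the sort markers, sex-linked genes and a group of osteoblast, adipocyte and matrix genes fixed in advance complete the set of 132 genes. Genes outside it are said to be chosen after their values were seen.

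The fit was tested on simulated data for the KO against WT comparison with 28607 probes, of which 200 were changed. At a log2 change of 1, 144 of the 200 were recovered with 6 false calls, and at a log2 change of 2, 187 of the 200 with 6 false calls. With 1 list shifted by -0.5, that list ranked 1 of 27 and 1 other list was called. The simulated probes were drawn independently of each other. These figures therefore do not cover genes that vary together across arrays, and cannot test the preset correlation used for the lists.

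All 6 arrays lay on 1 slide with 1 scan, so slide and scan could not be fitted as batches. The 3 WT arrays lay on 1 side of the slide and the 3 KO arrays on the other, so side and group cannot be told apart. No spots were saturated, and no pair of arrays held identical signals. The 75th percentile of the processed signal lay between 953 and 1247 over the arrays. The SD of the negative control spots was 7.5, 7.2 and 6.3 on the WT arrays and 9.7, 15.3 and 10.0 on the KO arrays. Alternatives were normexp background correction with an offset of 50 and quantile normalization, quantile normalization of the processed signals, centring on the median, no filter and a stricter filter on dim probes, the replicate number as a block, the deposited log2 table, an intensity trend with robust variance, array weights, each replicate left out in turn, marked spots kept, the mean of a gene's probes, and other fold and p thresholds. A term for the sex read from Xist and Y-linked signal and a fit without the 2 arrays with Xist signal were added after seeing the data. The number of arrays limits the precision.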

Results

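The arrays compared cultured bone marrow stromal cells of 3 KO and 3 WT samples. The aim was to show how the transcriptome of these cultures differs when the long non-coding RNA NONMMUT002667 is lost. Bone marrow stromal cells are the marrow's non-haematopoietic adherent cells, from which osteoblasts and adipocytes arise. Over the WT arrays, 54.3%, 56.1% and 56.7% of non-control spots were well above background, and over the KO arrays 53.02%, 52.1% and 49.0%. Log2 signals correlated between arrays with r from 0.988 to 0.994 across probes, which are not independent replicates. The first principal component held 40.6% of the variance and placed all 3 WT arrays on one side (-24.7, -26.9 and -22.6) and all 3 KO arrays on the other (16.7, 34.8 and 22.7).

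The knocked-out RNA itself could not be identified on the arrays, because 0 spots carried the name of a NONMMUT transcript, so the knockout labels were not checked on the target. A probe over it under another name, or without a gene name, was not searched for by position. The sort markers did not differ between groups by limma. Ly6a, which encodes Sca-1, had values of 3.48 ± 0.47 in WT and 3.40 ± 0.27 in KO (SD, n = 3 each; limma adjusted p = 0.911), and Itgb1, which encodes CD29, 5.49 ± 0.10 and 5.41 ± 0.17 (limma adjusted p = 0.766). Transcripts of the 2 markers that the sort excluded were well above background on all 6 arrays. Ptprc, which encodes CD45, had 3.32 ± 0.10 in WT and 3.52 ± 0.22 in KO (limma adjusted p = 0.519) by its representative probe. Its 4 other tested probes had log2 differences from 0.25 to 0.52, with all KO values above the WT values (unadjusted limma p from 0.00491 to 0.0459, limma adjusted p from 0.138 to 0.312). Itgam, which encodes CD11b, had 4.02 ± 0.14 and 4.14 ± 0.10 (limma adjusted p = 0.615), though a second Itgam probe had a difference of -0.25. Of the 26 macrophage and monocyte markers tested, 25 were well above background on all 6 arrays. Their median level over both groups was 4.78, against 1.95 for skeletal stem and stromal progenitor markers and 1.61 for osteoblast lineage genes. Probes can differ in brightness for other reasons, so these levels do not give shares of cells. All 6 samples are labelled male. Xist, the RNA that coats the inactive X chromosome of female cells, was well above background on the arrays of WT replicate 3 (-0.53) and KO replicate 1 (-0.36) and not on the other 4, where it lay between -6.84 and -5.86. The Y-linked gene Eif2s3y was not well above background on those 2 arrays and lay between 1.04 and 1.17 on the other 4 by its brighter probe. One Kdm5d probe did not follow this split, with values from -1.07 to -0.89 on all 6 arrays.

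**Figure D1:**
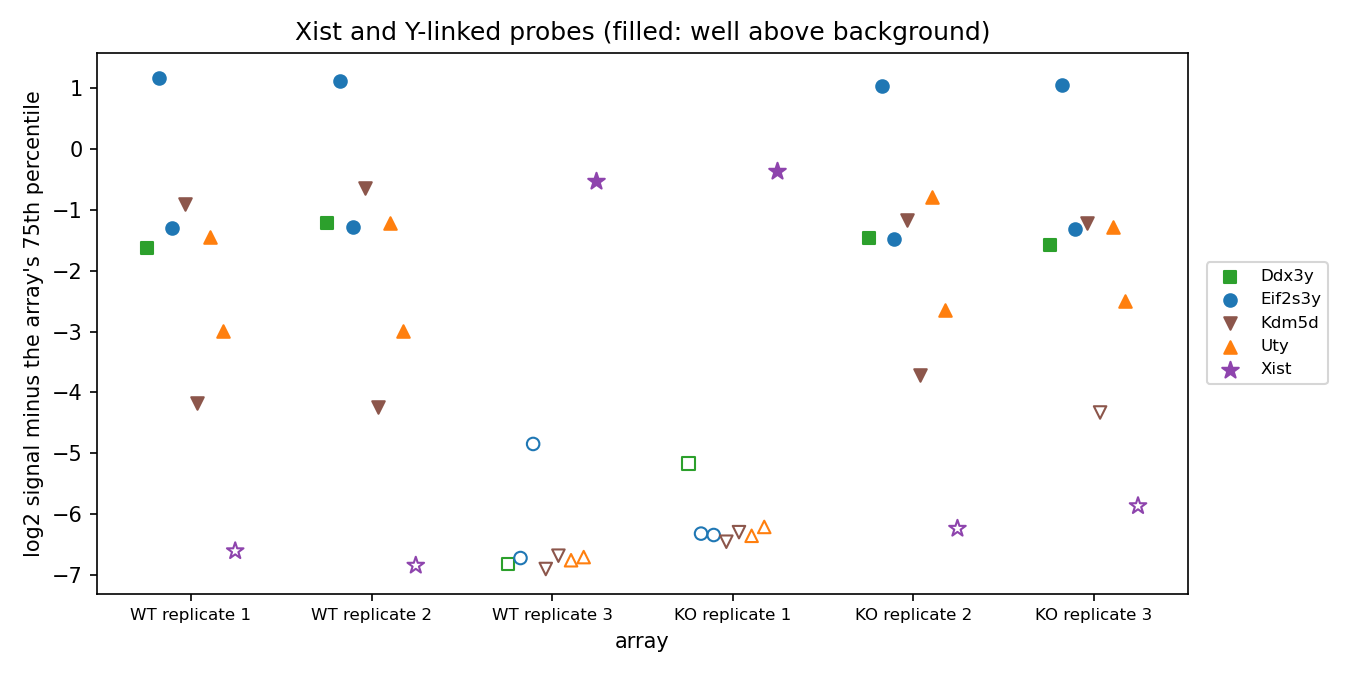
Log2 signal relative to the array's 75th percentile (vertical axis) of Xist and of 7 probes of 4 Y-linked genes on each of the 6 arrays (horizontal axis). Filled symbols are well above background. Xist is filled on WT replicate 3 (-0.53) and KO replicate 1 (-0.36), where no Y-linked symbol is filled.

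In KO cells, 10 genes were lower and 2 higher than in WT cells among 15324 tested (limma, adjusted p under 0.05). Fmod, Ibsp and Phospho1, of the skeleton's matrix and mineral, were among the lower genes, a grouping made after the calls and not tested. Fmod, which encodes the collagen-binding proteoglycan fibromodulin, fell 5.38-fold, from 1.95 ± 0.25 in WT to -0.48 ± 0.44 in KO (log2 difference -2.43, SE 0.23, n = 3 each; limma adjusted p = 0.0496; probe on chromosome 1, 135943998 to 135944057, mm9). Ibsp, which encodes bone sialoprotein, fell 3.32-fold, from 5.31 ± 0.23 to 3.58 ± 0.23 (log2 difference -1.73, SE 0.16; limma adjusted p = 0.0496; chromosome 5, 104739720 to 104739779). Phospho1, a phosphatase of mineralising matrix vesicles, was not well above background on any KO array and was at least 1.51-fold lower in KO (limma adjusted p = 0.0496; chromosome 11, 95692092 to 95692151).

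Among the lower genes measured on KO arrays, the largest log2 difference was that of Lrmda, a leucine-rich repeat gene linked to melanocyte differentiation, which fell 9.02-fold (log2 difference -3.17, SE 0.29; limma adjusted p = 0.0496; chromosome 14, 23875251 to 23875310). Of its 3 other tested probes, 1 that overlaps this position fell by 3.22 on the log2 scale (limma adjusted p = 0.0496). The other 2, at starts 23403754 and 23418369, were not well above background on any KO array and were at least 7.24-fold and at least 1.21-fold lower, and the first of them passed. Flvcr2, a membrane transporter, fell 2.51-fold (log2 difference -1.33, SE 0.09; limma adjusted p = 0.0348; chromosome 12, 87154338 to 87154397), and Mtcl1, a microtubule cross-linking factor, 1.98-fold (log2 difference -0.98, SE 0.10; limma adjusted p = 0.0496; chromosome 17, 66686499 to 66686558). The representative probes of Smim5, Kcnf1, Sgca and Chrna1 were not well above background on any KO array. They were at least 1.12-fold, 1.16-fold, 2.94-fold and 1.17-fold lower in KO, with limma adjusted p = 0.0348 for Smim5 and 0.0496 for the others. A second Sgca probe was well above background on 1 KO array and had a log2 difference of -1.88 (limma adjusted p = 0.149). Sgca encodes the muscle membrane protein alpha-sarcoglycan and Chrna1 a subunit of the muscle acetylcholine receptor.

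Of the 2 higher genes, Krtap13-1, a keratin-associated protein gene, was not well above background on any WT array and was at least 4.88-fold higher in KO (limma adjusted p = 0.0496; chromosome 16, 88729718 to 88729777). Wdfy1, a FYVE-domain protein of endosomes, rose 1.78-fold by its representative probe (log2 difference 0.83, SE 0.08; limma adjusted p = 0.0496; chromosome 1, 79700817 to 79700876), but its 3 probes disagreed, with log2 differences of 0.83, 0.82 and -0.60. The next 3 genes by p on the higher side did not pass: Gatm, the first enzyme of creatine synthesis (log2 difference 0.72, limma adjusted p = 0.0534), Cox7b2 (1.14, limma adjusted p = 0.0565) and St8sia5 (1.15, limma adjusted p = 0.059).

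Over all probes, 17 passed (14 lower, 3 higher in KO) of 28607. Probes of Lifr (-0.94), Ube4a (1.30) and Col22a1 passed without being the representative probe of their gene, and are named after their values were seen. The Col22a1 probe was not well above background on any KO array and was at least 1.42-fold lower, and the representative probe of Ube4a had the other sign (-0.28). Without the threshold on the adjusted p, 2293 genes had an unadjusted limma p under 0.05 (1061 higher, 1232 lower; 733 higher and 1302 lower with median centring), and 211 of them differed at least 2-fold (19 higher, 192 lower). The 3 KO values lay outside the range of the 3 WT values, all on one side, in 22.4% of genes. A share of 10% is the average over all splits of the arrays. Genes vary together across arrays, so 1 split can lie far from that average and the excess was not tested. The filter on dim probes also used the real groups, which can raise the share for the real split. The count of 12 rests on adjusted p close to the threshold: it was 0 without WT replicate 1 (2044 genes at an unadjusted limma p under 0.05) or WT replicate 2 (1787 at that p), 5 without WT replicate 3, 8 without KO replicate 1, 1 without KO replicate 2 and 2 without KO replicate 3. It was 141 with normexp and quantile normalization, 66 with median centring, 121 with a variance trend and 2 with the mean of a gene's probes. Without the filter on dim probes it was 0 (7744 at an unadjusted p under 0.05, 6541 higher and 1203 lower). It was also 0 with the replicate number as a block (2346 at that p) and with a sex term (2400 at that p), and 3 without the 2 arrays with Xist signal. Some probes not well above background on any array read higher in KO, such as 1 of Uty (-6.77 in WT, -6.17 in KO) and 1 of Ddx3y (-6.77 and -6.18). With the filter there were 1061 higher and 1232 lower genes at an unadjusted limma p under 0.05. The higher side thus grew with the dim probes that the filter leaves out, while the lower side did not. How many of the 6541 higher genes read at the floor was not tested.

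The osteoblast lineage list was lower in KO as a group. Of 25 members tested, 23 had a negative difference, with a median log2 difference of -0.71 (95% bootstrap interval -1.12 to -0.60). Camera in limma called the list lower (adjusted p = 2.19e-14), but with an estimated correlation the adjusted p was 0.634 (unadjusted p = 0.0406). The adjustment gave the other called lists that same 0.634. Fry gave an adjusted p of 0.157 (unadjusted p = 0.00581). One member, Ibsp, passed over all genes tested. Adjusted over the list alone, 17 members fell and 1 rose. Bglap, which encodes osteocalcin, fell by that count (log2 difference -1.76, SE 0.37), as did Runx2 (-1.24, SE 0.25) and Sp7 (-0.65, SE 0.17), the transcription factors that direct osteoblast formation, and Alpl, the bone alkaline phosphatase (-0.63, SE 0.22). Dlx3 (-0.60, SE 0.08), Ifitm5 (-1.85, SE 0.28) and Bmp2 (-1.12, SE 0.19) fell by it too. From Bglap to Bmp2, none passed over all genes, with limma adjusted p from 0.0593 for Dlx3 to 0.246 for Alpl. The largest falls by that count were those of Phex (-2.61) and Dmp1 (-2.54), genes of late osteoblasts and osteocytes that are named here after their values were seen. Spp1, which encodes osteopontin, was the member that rose by the count over the list alone (0.25, SE 0.09; limma adjusted p = 0.259 over all genes). Probes disagreed for Runx2 (-1.24, -0.75 and 0.07) and differed in size for Col1a1, the main collagen of bone (-0.90 by the representative probe, -0.21 and -0.14 by the others). Beside this list, the macrophage and monocyte markers had a median of 0.12 and the skeletal stem and stromal progenitor markers one of 0.02.

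**Figure D2:**
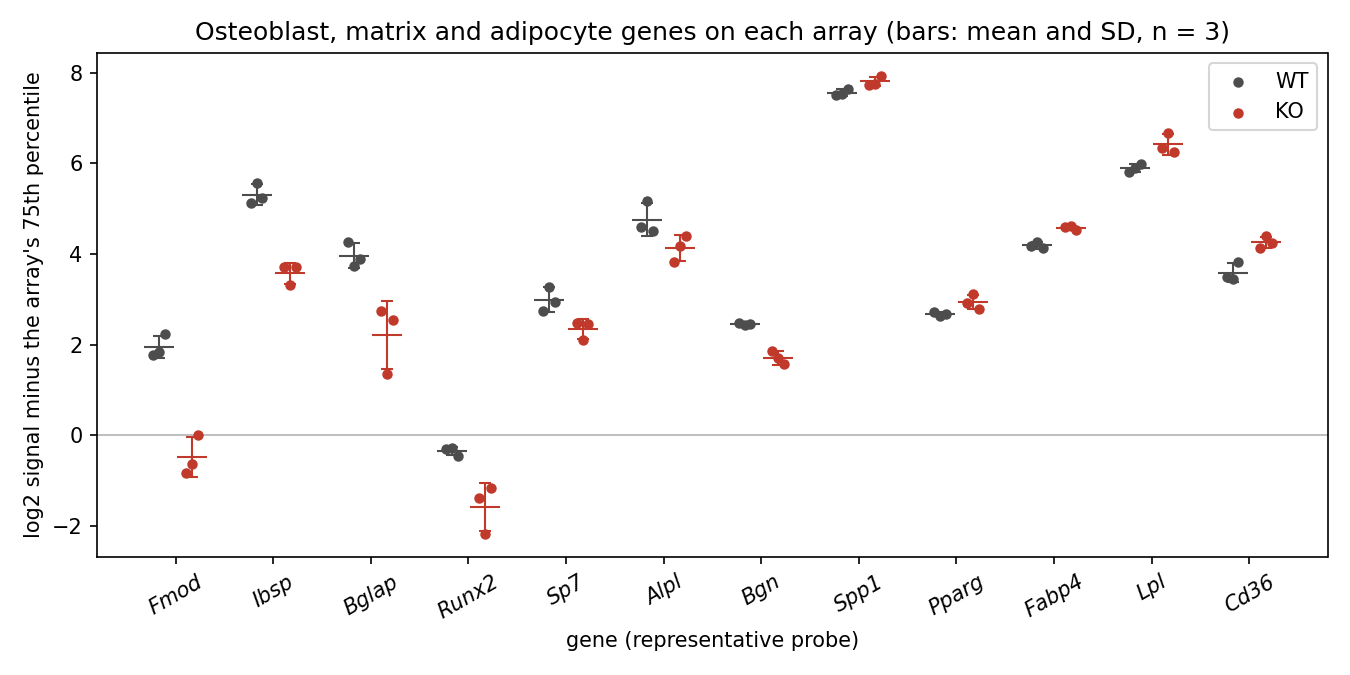
Log2 signal relative to the array's 75th percentile (vertical axis) of 12 genes (horizontal axis) on each WT (grey) and KO (red) array. Points are arrays, and bars are the mean and SD of 3. Fmod lies at 1.95 ± 0.25 in WT and -0.48 ± 0.44 in KO, and each of the first 7 genes has its 3 KO points below its WT points, whereas the last 5 have theirs above. The 12 genes were picked for display. Of adipocyte genes not shown, Cebpa (log2 difference 0.07) and Adipoq (-0.41) overlapped between groups, and Dgat2 (-0.26) had its KO values below its WT values.

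The extracellular matrix and small leucine-rich proteoglycan list was lower (28 tested, 22 negative, median -0.28; camera in limma adjusted p = 2.20e-05; adjusted p = 0.634 with an estimated correlation). Fmod passed over all genes, and adjusted over the list alone 7 members fell and 0 rose. Bgn, which encodes the proteoglycan biglycan, had a log2 difference of -0.74 (SE 0.09; limma adjusted p = 0.0593 over all genes) by its representative probe and -0.02 by its other probe. Col5a2 (-1.07, SE 0.19) fell adjusted over the list alone, as did Col14a1 (-1.27, SE 0.20), which was well above background on 1 KO array. The matrix remodelling list was also lower (23 tested, 17 negative, median -0.28; camera in limma adjusted p = 0.00701; adjusted p = 0.634 with an estimated correlation). Adjusted over the list alone, 4 of its members fell and 2 rose, and 0 passed limma over all genes (8 lower and 3 higher at an unadjusted p under 0.05). The gelatinase gene Mmp2 fell by that count (-0.78, SE 0.11) and Plau, the urokinase gene, rose (0.44, SE 0.09). Without KO replicate 1, both lists lost their call (camera in limma adjusted p = 0.0501 for each), with medians of -0.13 for the matrix list and -0.30 for the remodelling list, and without the 2 arrays with Xist signal the remodelling list did (adjusted p = 0.0594). The median of the matrix list was -0.18 without WT replicate 2, -0.48 without WT replicate 3 and -0.50 without KO replicate 3, -0.107 with probes well above background on all 6 arrays and -0.153 with normexp and quantile normalization, and that of the remodelling list -0.145 without KO replicate 2.

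The Wnt signalling list was lower (25 tested, 23 negative, median -0.21; camera in limma adjusted p = 0.000153; adjusted p = 0.634 with an estimated correlation). Adjusted over the list alone, 3 members fell, and 0 passed limma over all genes (7 lower at an unadjusted p under 0.05). Tcf7, a transcription factor of the pathway, had a log2 difference of -0.84 (SE 0.12), Wnt10b -0.57 (SE 0.14), Wnt4 -0.96 (SE 0.27) and the receptor gene Fzd1 -0.62 (SE 0.15). The list's median was -0.125 without KO replicate 1 and -0.135 without KO replicate 2, and -0.106 without the filter on dim probes.

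Cell cycle and proliferation genes were the one list higher in KO by camera. All 33 members tested had a positive difference, of a small size (median 0.27, 95% bootstrap interval 0.22 to 0.29; camera in limma adjusted p = 1.53e-08; adjusted p = 0.634 with an estimated correlation). None passed limma over all genes or adjusted over the list alone, and 11 had an unadjusted p under 0.05. The examples with the smallest p were Pcna, the replication clamp (0.29, SE 0.08), Ccne1 (0.29, SE 0.09), the mitotic kinase gene Cdk1 (0.40, SE 0.12) and Mcm6 (0.27, SE 0.09, and 0.02 by a second probe). Without WT replicate 3 the list's median was 0.18, and the mean over its members was 2.47 on both WT replicate 1 and KO replicate 2. With an estimated correlation camera called 0 of the 27 lists (1 at an unadjusted p under 0.05), fry called 0 (4 at that p), and camera at the preset correlation called up to 7 lists in other splits of the same 6 arrays.

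**Figure D3:**
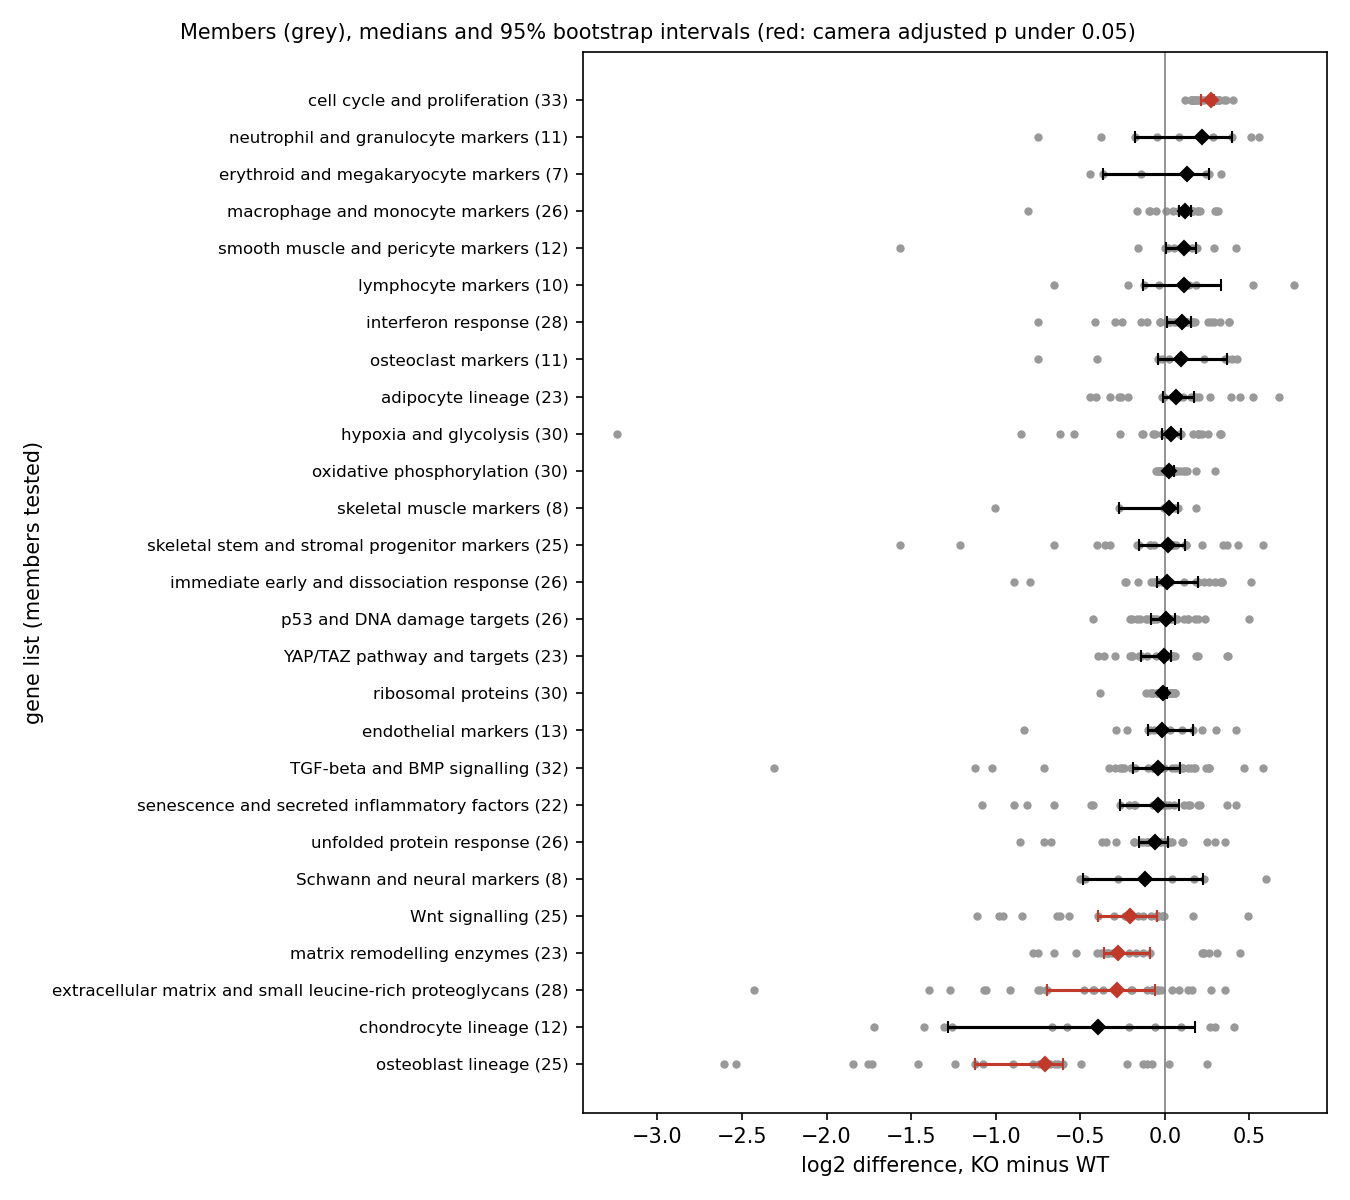
Log2 difference between KO and WT (horizontal axis) for the members of each of the 27 gene lists (vertical axis, with the number of members tested). Grey points are genes, diamonds are medians with 95% bootstrap intervals over members, and red marks the 5 lists called by camera at the preset correlation. The osteoblast list has the lowest median (-0.71) and the cell cycle list the highest (0.27).

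Adipocyte lineage genes were not called as a list (23 tested, median 0.07; camera in limma adjusted p = 0.434), and adjusted over the list alone 3 members rose and 0 fell. These were Cd36, a fatty acid receptor (log2 difference 0.67, SE 0.13), Fabp4, a fatty acid binding protein (0.39, SE 0.08), and Lpl, lipoprotein lipase (0.52, SE 0.13). None of the 3 passed over all genes (limma adjusted p = 0.0927, 0.0945 and 0.141). With 25 of 26 macrophage and monocyte markers also well above background on all 6 arrays, which cells these transcripts came from was not tested. Pparg, the main transcription factor of adipocytes, had a difference of 0.27 (SE 0.10; limma adjusted p = 0.273), Cebpa 0.07 (SE 0.12) and Adipoq -0.41 (SE 0.48, well above background on 1 KO array). Wwtr1, which encodes the coactivator TAZ, had -0.39 (SE 0.14; limma adjusted p = 0.254) and Tgfb1 -0.05 (SE 0.14; limma adjusted p = 0.900).

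The other lists did not pass (camera in limma adjusted p from 0.07 to 0.882). Median log2 differences were -0.39 for chondrocyte genes, 0.12 for macrophage and monocyte markers, -0.06 for the unfolded protein response, -0.04 for both TGF-beta and BMP signalling and senescence, and 0.00 for the YAP/TAZ pathway. They were 0.01 for p53 targets, 0.10 for the interferon response, 0.03 for oxidative phosphorylation, 0.03 for hypoxia and glycolysis, -0.01 for ribosomal proteins and 0.01 for immediate early genes. Among cell type markers the medians were 0.10 for osteoclasts, 0.22 for neutrophils, 0.11 for lymphocytes, 0.13 for erythroid cells and megakaryocytes, -0.02 for endothelium, 0.11 for smooth muscle and pericytes, 0.03 for skeletal muscle, -0.12 for Schwann and neural cells and 0.02 for stromal progenitors. For the stromal progenitor, smooth muscle, skeletal muscle, endothelial, p53 and hypoxia lists, the median, the mean and the direction of the test did not share 1 sign. In the chondrocyte list, Col11a2 (-1.72, SE 0.27), Col11a1 (-1.42, SE 0.26) and Comp (-1.26, SE 0.27) fell adjusted over the list alone, and the list passed without WT replicate 3 (adjusted p = 0.0218) or KO replicate 3 (adjusted p = 0.0124). Its median was -0.0978 without WT replicate 1 (adjusted p = 0.208) and -0.13 without KO replicate 2 (adjusted p = 0.0961). The macrophage list passed, upward, without WT replicate 1 (adjusted p = 0.0153) or KO replicate 3 (adjusted p = 0.0197). The interferon list passed, upward, without WT replicate 1 (adjusted p = 0.022) or KO replicate 2 (adjusted p = 0.0356), and the unfolded protein response list, downward, without KO replicate 3 (adjusted p = 0.0476). Some of these lists also passed under other processing.

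Single members of these lists also moved when adjusted over the list alone, and of these Chrna1, a skeletal muscle marker, was the one that passed over all genes. Among stromal progenitor markers, Grem1 (log2 difference 0.58) and Kitl (0.44) rose by that count, while Nt5e (-1.21) and Cspg4 (-1.56) fell, though the Kitl probes did not share 1 sign. In TGF-beta and BMP signalling, Bmp7 (-2.31, well above background on 1 KO array), Bambi (-1.02) and Bmp2 fell and Grem1 rose. In the unfolded protein response list, Trib3 (-0.86) and Ddit3 (-0.67) were among the 3 that fell, and 1 member rose, though a second Ddit3 probe had -0.02. Car12, a carbonic anhydrase, was among the 3 hypoxia and glycolysis genes that fell (-3.24, well above background on 2 KO arrays), Klf4 (-0.80) was 1 of 2 immediate early genes that fell, and Cdkn2a (-0.65) and Cdkn1a (-0.43), inhibitors of the cell cycle, were among the 3 senescence genes that fell, though another Cdkn1a probe had -0.01, and Hgf rose (0.42). Tnfrsf11a, which encodes the receptor RANK, rose in the osteoclast list (0.40).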

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

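The fits with a sex term and without the 2 arrays with Xist signal were chosen after seeing the data. All 12 genes past the threshold kept their direction under each alternative that tested them. Their KO and WT values did not overlap, so leaving out arrays could not reverse them. The replicate block and the sex term, balanced over the groups, could not either. The count of genes past the threshold in limma, 12 with 17 probes, moved as follows: 141 genes and 215 probes with normexp and quantile normalization, 21 and 33 with quantile normalization of processed signals, 66 and 109 with median centring, 121 and 180 with an intensity trend and robust variance, 19 and 28 with array weights, 6 and 9 among probes above background on all 6 arrays, and 2 genes with the mean of a gene's probes. It was 0 genes and 0 probes without the filter on dim probes (7744 genes at an unadjusted p under 0.05) and with a sex term (2400 at an unadjusted p under 0.05), and 3 genes and 7 probes without the 2 arrays with Xist signal. An unadjusted p under 0.05 with at least 2-fold gave 211 genes. Leaving out each replicate in turn gave 0 to 8 genes and 0 to 12 probes. The deposited values gave 12 genes, of which 10 were the same genes. The stricter filter tested fewer genes and the leave-one-out fits fewer samples. For the other moves the cause was not tested.

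The number of lists called, 5 by camera, was 10 without the filter on dim probes, 8 with an intensity trend, 3 to 8 with each replicate left out, and 0 with an estimated correlation and with fry. Lists not called otherwise passed, with camera's adjusted p, as follows. Without the filter on dim probes these were the unfolded protein response (0.0015), YAP/TAZ (0.00429), TGF-beta and BMP (0.00673), ribosomal protein (0.0374) and p53 (0.0427) lists, each lower. With an intensity trend they were the unfolded protein response (0.0432) and chondrocyte (0.0444) lists, lower, and the macrophage list (0.035), higher. With probes above background on all 6 arrays it was the unfolded protein response list (0.0456). The osteoblast list was called in all 19 alternative fits with camera at the preset correlation (adjusted p from 4.56e-16 to 2.49e-11). These fits draw on the same 6 arrays and share that correlation, so they are not independent of each other.

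Replicate numbers were shared between groups, but did not pair the samples: same-numbered samples' deviations from their group means correlated with r = 0.0554, 0.154 and -0.0319 across probes, and not every sample correlated best with its own number. With the replicate number as a block, limma called 0 genes and 0 probes (2346 genes at an unadjusted p under 0.05), and camera 5 lists. A block for slide or scan was not run, since there was 1 slide and 1 scan.

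Genes and lists that were not called changed direction in some fits. With each replicate left out, log2 differences ran from -0.166 to 0.0674 for gene Tgfb1, -0.258 to 0.182 for gene Ly6a, -0.0777 to 0.0130 for gene Kdm5d, -0.863 to 0.0229 for gene Adipoq, -0.0353 to 0.141 for gene Cebpa and -0.138 to 0.0106 for gene Itgb1. The value for gene Itgam was -0.0641 with the mean of its probes. Camera's adjusted p of reversed lists without the filter on dim probes was 0.677 for skeletal muscle, 0.656 for smooth muscle, 0.568 for adipocyte, 0.572 for oxidative phosphorylation, 0.566 for interferon, 0.296 for immediate early and 0.183 for hypoxia. Without the 2 arrays with Xist signal it was 0.428 for interferon and 0.999 for neutrophil markers. For hypoxia it was 0.977 with quantile normalization, 0.969 with the deposited values and 0.662 with the mean of probes. With each replicate left out, lists that reversed in some fit ran from 0.022 to 0.673 for interferon, 0.119 to 0.72 for ribosomal proteins, 0.357 to 0.989 for stromal progenitors, 0.395 to 0.775 for neutrophils, 0.288 to 0.92 for endothelium, 0.535 to 0.917 for immediate early and 0.759 to 0.92 for hypoxia. The cause was not tested. Probes close to background limit what can be read from the dimmest genes.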

Other observations

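Apart from Cd74, the genes in the first 2 paragraphs, and all the tests in the rest, were chosen after the results were seen. The classical MHC class II genes, which present antigen on the surface of myeloid and B cells, were measured at lower mean values in KO. None passed limma, and they were not tested as a set. The 4 probes of H2-Ab1 had log2 differences from -0.87 to -0.72, with limma adjusted p from 0.0723 to 0.19. H2-Eb1 had -0.83 (limma adjusted p = 0.0887), H2-Aa -0.86 (well above background on 2 KO arrays, limma adjusted p = 0.444) and the invariant chain gene Cd74 -0.81 (limma adjusted p = 0.122). For H2-Aa the KO and WT values overlapped. H2-DMa (0.11) and H2-DMb1 (0.06), whose products load peptides, did not share this sign.

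Tmem119 (log2 difference -1.16, limma adjusted p = 0.0689) and the channel gene Panx3 (-1.15, limma adjusted p = 0.0691), bone genes outside the lists, had negative differences that did not pass. Bone genes outside the lists were not counted or tested as a set. Tnfrsf11b, which encodes the decoy receptor osteoprotegerin, had a difference of 0.01 (limma adjusted p = 0.986). Of the 6 tested probes of the potassium channel gene Kcnma1, 4 had log2 differences from -1.21 to -0.98, 1 had 0.07 and 1 was not well above background on any KO array. Both probes of Cd59a, a complement inhibitor, were measured higher in KO (0.77 and 0.75, limma adjusted p = 0.0689 and 0.0534), and the 3 probes of Entpd4 lower (-0.72, -1.12 and -0.75).

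The osteoblast lineage list was lower in KO, with a median log2 difference of -0.71, called at camera's preset correlation and not at an estimated one (adjusted p = 0.634). A lower share of all stromal cells in the KO samples would lower stromal progenitor markers as well, but their median was 0.0179, with a bootstrap interval from -0.155 to 0.117. The osteoblast and progenitor lists share 0 members. This cannot decide on a change in cell mix, since progenitor members went both ways (14 positive, 11 negative) and 4 are also in the smooth muscle and pericyte list. Macrophage and monocyte markers leaned higher in KO (21 of 26 positive, median 0.12). A loss of osteoblast-lineage cells alone was not tested. Mice of both sexes in the groups do not account for the size of the osteoblast difference, since without the 2 arrays with Xist signal, 1 in each group, the osteoblast median was -0.767 (-0.78 to -0.649 over all alternatives). The side of the slide cannot be told apart from the group, because 0 sides held arrays of both groups. An earlier stage of osteoblast maturation in the KO cells may be a reason, which was not tested.

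Xist signal without Y-linked signal was measured on WT replicate 3 and KO replicate 1, although all samples are labelled male. On those 2 arrays Eif2s3y read -6.72 and -6.32 by its brighter probe, against 1.04 to 1.17 on the others. Such values argue against the male label for the RNA on these 2 arrays, though 1 Kdm5d probe read alike on all 6 arrays. A female mouse in each group is a candidate source that stays open. On 6 of 6 arrays exactly 1 of Xist and the Y-linked probes that were not above background everywhere was measured. That count restates the signals that raised the question. A sample from outside the study's male mice stays open.

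Lrmda was lower in KO. A sequence difference under a single probe is argued against by a probe that does not overlap the representative one, which was at least 7.24-fold lower. The 7 other tested genes within 1 Mb had a median log2 difference of 0.0842 (quartiles -0.318 and 0.111). All but Kcnma1 lie on 1 side of Lrmda, at starts 22490755 to 22803259, with log2 differences from -0.338 to 0.300. These values argue against loss of a wider stretch of the chromosome that reaches those genes. Kcnma1, on the other side, was the 1 neighbour that was at least 2-fold lower (limma adjusted p = 0.105). A change that reaches Lrmda and Kcnma1, or a loss on that side, may therefore remain, which was not tested.

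The 6 arrays can be split into 2 groups of 3 in 10 ways, too few for a share of splits under 0.05. All 10 splits used the probes kept by the filter on the real WT and KO groups, which can favour the real split. Among probes well above background on all 6 arrays, a filter blind to the groups, the real split gave 6 genes. The other splits were not run with that filter. The real split gave 12 genes and 17 probes by limma, as many as in 1 of the 10 splits (itself), and the highest of the other splits gave 0 of each, with 184 to 1770 genes at an unadjusted p under 0.05 against 2293. By camera, the real split called 5 lists, and 5 of the 10 splits called at least as many, with 7 as the highest of the others. The size of the osteoblast median was 0.706 in the real split and at most 0.44 in the others, so 1 of the 10 splits reached it. Camera at the preset correlation gave this list an unadjusted p of 8.1e-16 in the real split. In other splits it also gave 2.46e-06, 3.65e-06, 4.17e-06 and 9.51e-06, and up to 0.867 in the rest.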
